A study of Homo sapiens with 16 samples.

How the data were processed

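RNA was measured by bulk sequencing in 16 libraries of NCI-H929 cells, 4 each of DMSO, degrader (compound 27, 3 nM, 6 h), NTC and p300 KO. Per the labels, RNA was extracted with a Qiagen QIAsymphony RNA kit, its integrity was checked on a TapeStation and libraries were made with the NEBNext Ultra II RNA kit; the integrity values are not given in the sources used here. The labels say neither how the KO was made nor whether the 4 replicates of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

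The deposited values were integer counts per gene, 1 table per library, with 57500 genes in each. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b, featureCounts of Subread 1.5.2 and DESeq2 1.16.1 were used with GRCh38. The use of strand in counting, the treatment of reads that map to several places and the annotation release are not stated. Values of antisense or overlapping genes such as KLLN, CD44-DT, LENG9, TNFRSF14-AS1 and MIR210HG are therefore uncertain, as are those of near-identical copies such as U1, RN7SL3 and histone genes. Of the 57500 genes, 41395 had a symbol. The positions were compared with GENCODE 29: 56898 identifiers matched, and 54784 of these (96.3%) had the same start, end and strand. No summary line or total entered the library sizes.

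Total counts ran from 12.6 M to 23.1 M (M, mega) per library. A gene with 0 counts could have had up to 3 counts, which is between 0.130 and 0.238 CPM depending on the library. Shares of counts in single libraries carry exact binomial 95% intervals; sequencing reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Pairs of libraries were checked for duplicates with a chi-square statistic per degree of freedom on their counts. It ran from 2.79 to 30.9 in the other pairs within a group, from 171 to 193 in pairs with degrader 2 and from 82.6 to 90.2 in pairs with p300 KO 1, and no pair of libraries was identical.

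Counts were analysed with edgeR 4.0.16 in R 4.3.3. Each comparison, degrader against DMSO and p300 KO against NTC, was fitted on its own 8 libraries. Genes were kept with filterByExpr at its defaults, libraries were scaled with TMM, and the quasi-likelihood test was run on group. The difference between the effects was the contrast of KO minus NTC less degrader minus DMSO in a fit on all 16 libraries. The SE of a log2 fold change was its absolute value divided by the square root of the F statistic of the quasi-likelihood test. Such an SE is not a separate estimate and can fall below counting error in genes with few counts. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold change. CPM values of genes are scaled with TMM within each comparison unless stated otherwise. Agreement between the comparisons was the Pearson correlation of log2 fold changes across the genes tested in both, with an exact p from all splits of the libraries of 1 experiment.

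24 gene lists were tested with camera of limma 3.58.1 with its preset correlation of 0.01, adjusted over the lists of a comparison. The lists were acetyltransferases and bromodomain readers, myeloma transcription factors, plasma cell surface proteins, immunoglobulin and secretory factors, MYC targets, p53 targets, S phase genes, mitosis genes, immediate early genes, MAPK output genes, NF-kB targets, interferon stimulated genes, MHC class I and class II genes, hypoxia (HIF) targets, unfolded protein response genes, ATF4 and amino acid genes, cholesterol synthesis genes, heat shock genes, the BCL2 family, glycine and nucleotide synthesis genes, ribosomal proteins, histone genes and mitochondrially encoded genes. H2AC18, H3C2, MT-RNR1 and MT-RNR2 had no match by symbol. The 7 marker lists covered earlier B cells, T cells, NK cells, monocytes, erythroid cells, fibroblasts and epithelia. Camera with the correlation estimated per list and fry were also run. Where members are given as adjusted over the list alone, the Benjamini-Hochberg step used only the members of that list.

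The comparisons, tests, lists, the rule for named genes and the first set of other settings were fixed before the data were examined. The rule names EP300, CREBBP, MYC and IRF4; up to 10 genes each way with the largest log2 fold change among called genes with a symbol, an average log2 CPM of at least 3 and no overlap between the libraries of the groups; up to 4 members per list with the smallest p; up to 6 genes each way in the difference; and up to 6 per direction called in both comparisons. Some names fall outside the rule and were chosen after their values were seen, many of them where 5 or fewer members of a list were called in a direction. They are ALDOC, FOS, DUSP1, ZFP36, IFIT3 and STAT2 with the degrader, PLK4, DDB2, POLK, FBXO22, CDC45, IER2, SRF, IER5, ETV4, CD83 and OAS2 in the KO, the list members named in the difference, and the genes beside EP300. Some genes that the rule or the lists include are not reported here. A symbol is shared by more than 1 gene for 1270 genes, and the identifiers kept these apart.

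These other settings were RLE, total count and upper quartile scaling, no filter on low counts, a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, a replicate block, immunoglobulin genes left out, a fit on all 16 libraries, an absolute log2 fold change of at least 1, the estimated correlation, fry, and each library left out in turn. After the data were seen, further settings were added: both mitochondria-rich libraries left out, mitochondrial genes left out, limma-voom with sample quality weights, the mitochondrial share as a covariate, and trends with GC content and gene length removed.

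The scripts were tested on simulated data with counts drawn from the means and library sizes of the real libraries, in which 200 genes changed by known folds, 50 at each of 1.5, 2, 3 and 4. Of these, 8%, 40%, 80% and 88% were called in the degrader comparison (15664 genes), 44%, 72%, 96% and 96% in the KO comparison (17098 genes) and 2%, 44%, 68% and 88% in the difference (17436 genes), none in the wrong direction. Of the genes called, 4.42%, 6.98% and 10.6% were false. With the mitochondria-rich libraries left out, the shares were 56%, 94%, 98% and 100% for the degrader, 74%, 96%, 98% and 100% for the KO and 54%, 80%, 96% and 100% for the difference. A further set of genes was raised 1.5-fold for a list test. Counts were drawn gene by gene around means shared by all libraries. The simulated data therefore lack shifts common to many genes in 1 library, and the shares called and false hold for simulated data only. The test on group labels split the libraries of each comparison in all 35 ways into groups of 4, and 100 splits, the labels and random ones, were used for the difference.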

Results

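The data were gene counts from bulk RNA sequencing of NCI-H929, a human multiple myeloma cell line, in 16 libraries that fall into 4 groups of 4. In the first experiment, cells received 3 nM of compound 27, a degrader of the p300 protein, or the solvent DMSO, and the treatment lasted 6 h. In the second, cells labelled p300 KO were set beside cells labelled NTC. A degrader is a small molecule that directs its target protein to the cell's own breakdown machinery. The protein p300 is a lysine acetyltransferase that acetylates histones and coactivates transcription; EP300 encodes it, and CREBBP encodes its close paralogue CBP. The labels put all libraries in batch 1. Total counts per library ran from 12.6 M to 23.1 M counts (M, mega). Their means were 18.3 ± 0.893 M in DMSO, 16.9 ± 2.96 M with the degrader, 22.1 ± 1.02 M in NTC and 20.1 ± 2.42 M in the KO (SD, n = 4 each). Between 23810 and 30119 genes had at least 1 count.

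Genes of the mitochondrial genome took a share of counts that set a pair of libraries apart. In degrader 2 the share was 64.9% (95% exact binomial interval 64.8 to 64.9%), and in p300 KO 1 it was 47.7% (47.7 to 47.8%). The other degrader libraries had 5.99% (5.98 to 6.00%), 6.29% (6.28 to 6.30%) and 6.96% (6.95 to 6.97%). The other KO libraries had 10.2% (10.2 to 10.2%), 10.7% (10.7 to 10.7%) and 11.4% (11.3 to 11.4%). The mean was 18 ± 4.47% in DMSO and 9.62 ± 0.558% in NTC (SD, n = 4 each). The lowest DMSO library, at 13.4% (13.4 to 13.4%), lay above those other 3 degrader libraries. After removal of mitochondrial counts, 4.42 M counts were left in degrader 2 and 8.66 M in p300 KO 1. These intervals cover counting error only. Both libraries stay in the main results, and counts without them stand beside the lists.

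**Figure D1:**
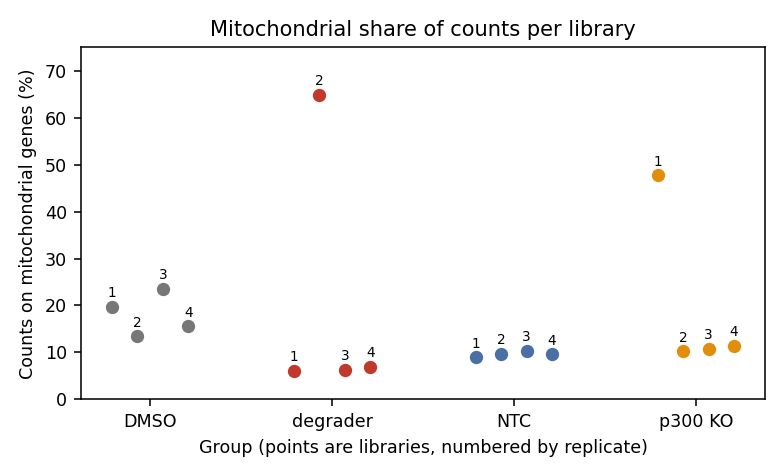
Percent of counts on mitochondrial genes (vertical axis) in each of the 16 libraries, by group; each point is a library and its number is the replicate. Degrader 2 (64.9%) and p300 KO 1 (47.7%) stand above the other libraries, and the 4 DMSO libraries stand above the other 3 degrader libraries.

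The first comparison asked which transcripts differ after 6 h with the degrader. EGR1, an immediate early transcription factor, rose from 5.09 ± 1.14 to 28.1 ± 1.52 CPM (mean ± SD, n = 4 each), a log2 fold change of 2.46 ± 0.16 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.83e-04). BHLHE40, a transcriptional repressor, had a log2 fold change of −2.75 ± 0.17 (adjusted p = 2.63e-04) and fell from 43.5 to 6.64 ± 1.75 CPM. MYL9, a regulatory light chain of myosin, had −2.73 ± 0.13 (adjusted p = 1.29e-04), and DDIT4, a stress-induced inhibitor of mTORC1, fell from 401 ± 64.1 to 81.0 ± 21.2 CPM (−2.30 ± 0.23, adjusted p = 0.00179). IRF4, a transcription factor on which myeloma cells depend, fell from 408 ± 26.4 to 222 ± 14.5 CPM (−0.88 ± 0.12, adjusted p = 0.00475), and each of the 4 treated libraries lay below each DMSO library.

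The other genes with the largest changes among well expressed genes were of many kinds. Those that rose were FAM3B, a secreted protein (log2 fold change 1.90 ± 0.27), ANXA6, an annexin (1.73 ± 0.21), RAB34, a small GTPase (1.68 ± 0.31), TAS1R3, a subunit of taste receptors (1.63 ± 0.15), and IL16, a cytokine (1.56 ± 0.13). So did CTAG2, a cancer-testis antigen (1.41 ± 0.22), PTP4A3, a protein tyrosine phosphatase (1.34 ± 0.19), and CTTN, which encodes the actin-binding protein cortactin (1.31 ± 0.20). Those that fell were FOSL2, a subunit of the AP-1 transcription factor (−2.37 ± 0.13), RHOBTB3, an ATPase of the Golgi (−2.26 ± 0.24), MARCKSL1, an actin-binding protein (−2.16 ± 0.14), and MIR210HG, the host transcript of a hypoxia-induced microRNA (−2.05 ± 0.16). MACC1, a regulator of MET expression (−1.99 ± 0.27), ADGRG5, an adhesion G protein-coupled receptor (−1.86 ± 0.23), and RGS3, which limits G protein signalling (−1.82 ± 0.12), fell as well. In leave-outs of 1 library, CTAG2 lost its call without DMSO 1, DMSO 4 or degrader 1 (adjusted p up to 0.0571), CTTN without DMSO 1 or DMSO 4 (up to 0.0525). RAB34 lost it in the 7 leave-outs that keep degrader 2 (up to 0.0852).

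**Figure D2:**
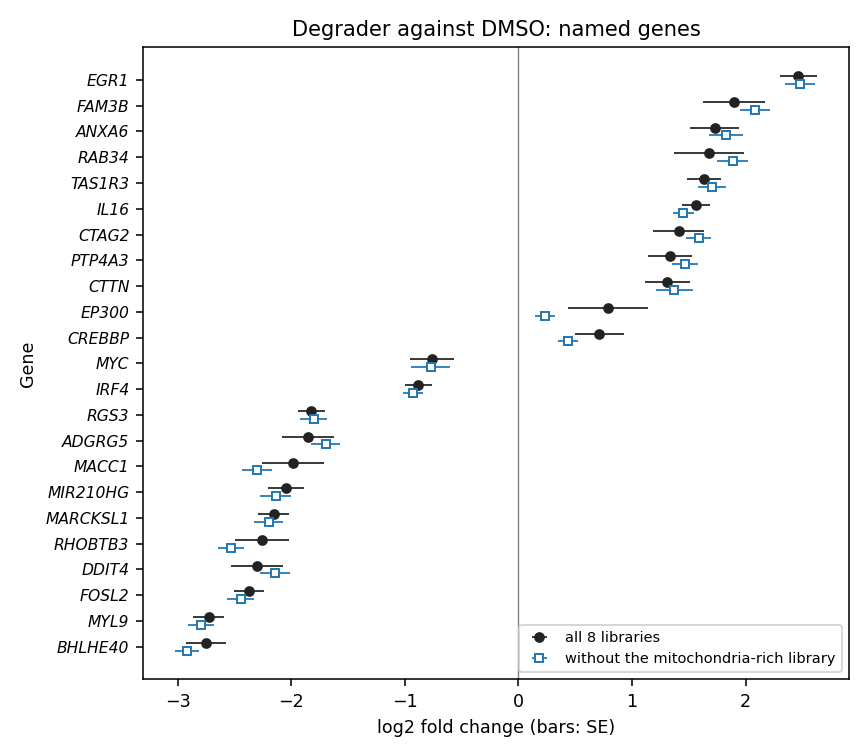
Log2 fold change, degrader against DMSO (horizontal axis), of the named genes (vertical axis) with all 8 libraries (filled circles) and without the mitochondria-rich library degrader 2 (open squares); bars are SE. BHLHE40 (−2.75) and EGR1 (2.46) lie at the ends, and EP300 moves from 0.79 to 0.24 when that library is left out.

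Targets of the hypoxia-inducible factor HIF were lower as a list: of 26 tested, 8 fell and 1 rose (median log2 fold change −0.12; camera adjusted p = 4.26e-06; adjusted p = 0.328 with an estimated correlation). Members that fell included PFKFB4, a regulator of glycolysis (−2.10 ± 0.17), STC2, a secreted stanniocalcin (−1.18 ± 0.11), and KDM3A, a histone demethylase (−0.91 ± 0.10), besides DDIT4. The glycolytic enzyme gene ALDOC rose (1.09 ± 0.25). Adjusted over the list alone, the same numbers of members fell and rose. Of 24 ATF4 and amino acid genes, 6 fell and none of the list rose over all genes tested (median −0.32; adjusted p = 1.3e-04; adjusted p = 0.328 with an estimated correlation). Among them were CEBPB, a stress-responsive transcription factor (−0.93 ± 0.14), and ASNS, the asparagine synthetase gene (−0.54 ± 0.11), and adjusted over the list alone 8 fell and 3 rose. Of 24 myeloma transcription factors, IRF4 and POU2AF1, a B cell coactivator (−0.53 ± 0.11), fell, and 22 were not called (median −0.25; adjusted p = 0.0247; adjusted p = 0.558 with an estimated correlation). When adjusted over the list alone, 7 fell and 1 rose. The call of this list was lost without DMSO 2 (0.0957), degrader 3 (0.0821) or degrader 4 (0.0973) and with total count scaling (0.0996). Without degrader 2 the counts fell and rose as follows: 10 and 3 of 27 hypoxia targets, 12 and 3 of the ATF4 genes, and 15 and 3 of the myeloma factors. ALDOC, ASNS and POU2AF1 lost their calls in the 7 leave-outs that keep degrader 2 (adjusted p up to 0.151, 0.141 and 0.142). CEBPB lost it without degrader 1 (0.0521).

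Lists of cell division genes were higher. Of 27 S phase genes, CHAF1A, a subunit of a histone chaperone for new DNA, rose (0.66 ± 0.12) and 26 were not called (median 0.30; camera adjusted p = 6.43e-04; adjusted p = 0.328 with an estimated correlation). Of 24 mitosis genes, MKI67, which encodes the proliferation marker Ki-67 (0.86 ± 0.16), and CDC20, an activator of the anaphase-promoting complex (0.53 ± 0.11), rose, and 22 were not called (median 0.40; adjusted p = 8.13e-04; adjusted p = 0.328 with an estimated correlation). Of 23 cholesterol synthesis genes, 1 rose and 22 were not called (list median 0.25; adjusted p = 0.00155; adjusted p = 0.466 with an estimated correlation). Of 17 histone genes, 2 rose, among them H2AC6 (0.94 ± 0.16), and 15 were not called (median 0.41; adjusted p = 0.00126; adjusted p = 0.328 with an estimated correlation). With members adjusted over the list alone, 1 S phase, 4 mitosis, 2 cholesterol and 6 histone genes rose and none of the 4 lists had a member that fell. Without degrader 2, 19 S phase, 14 mitosis and 15 cholesterol genes rose and none fell. The histone list was then not called (median 0.07, adjusted p = 0.0716; 6 rose and 5 fell). CHAF1A and CDC20 lost their calls in the 7 leave-outs that keep degrader 2 (adjusted p up to 0.0758 and 0.146), and MKI67 in 6 of them, all but that of degrader 1 (up to 0.0860). H2AC6 lost its call in 5, without DMSO 1, DMSO 4, degrader 1, degrader 3 or degrader 4 (up to 0.0668).

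Other lists held called members in both directions and were not called by camera. Of 16 immediate early genes (median −0.34, adjusted p = 0.19), 3 rose, namely EGR1, FOS, an AP-1 subunit (1.71 ± 0.30), and DUSP1, a phosphatase that inactivates MAP kinases (1.46 ± 0.31). Another 4 fell, namely the AP-1 subunit gene JUN (−1.23 ± 0.10), the orphan nuclear receptor gene NR4A1 (−1.29 ± 0.20), ZFP36, which promotes mRNA decay (−1.41 ± 0.25), and the antiproliferative gene BTG2 (−0.97 ± 0.14). Of 14 MAPK output genes (0.23, 0.258), ETV5, DUSP4 and SPRED1 rose (0.82 ± 0.13, 0.93 ± 0.18 and 0.64 ± 0.12), and the phosphatase gene DUSP5 fell (−0.90 ± 0.15). Of 21 NF-kB targets (−0.12, 0.137), BCL3, the interleukin 10 receptor gene IL10RA and the chemokine gene CCL3 fell (−1.60 ± 0.19, −1.37 ± 0.18 and −0.86 ± 0.19), and CD83 rose (1.20 ± 0.25). Of 25 interferon stimulated genes (0.08, 0.759), OAS1 and IFI6 rose (1.25 ± 0.18 and 0.93 ± 0.12). From the same list, IRF7, OASL, IFIT3 and STAT2 fell (−1.0 ± 0.10, −1.32 ± 0.22, −1.39 ± 0.26 and −0.53 ± 0.12). Members adjusted over the list alone rose and fell as 3 and 5, 5 and 2, 3 and 5, and 5 and 5 in these lists. FOS, DUSP1, ZFP36, CCL3, CD83 and IFIT3 lost their calls in the 7 leave-outs that keep degrader 2 (adjusted p up to 0.137). SPRED1 and STAT2 lost them in 6 of these, all but that of DMSO 3 (up to 0.147). ETV5 and DUSP4 lost them without DMSO 1, DMSO 4, degrader 1, 3 or 4 (up to 0.0876) and DUSP5 without DMSO 4, degrader 1, 3 or 4 (0.0594). NR4A1 lost its call without DMSO 1, DMSO 4 or degrader 4 (0.0525) and OASL without DMSO 4, degrader 1 or degrader 3 (0.0595). Without degrader 2, the NF-kB list was called lower (−0.21, adjusted p = 0.00404; adjusted p = 0.303 with an estimated correlation; 9 fell and 4 rose). In the same setting 3 immediate early, 5 MAPK output and 8 interferon stimulated genes rose and 6, 3 and 6 fell, and the median of the interferon list turned to −0.04.

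Of 57 MYC targets (median 0.12, camera adjusted p = 0.20), NOP56, a protein of ribosome assembly (0.83 ± 0.14), and the kinase gene MAP3K6 (1.38 ± 0.26) rose, and the hexokinase gene HK2 fell (−0.82 ± 0.11). Of 28 p53 targets (0.14, 0.482), the repair gene XPC rose (0.64 ± 0.14) and BTG2 fell. Of 23 plasma cell surface proteins (0.15, 0.517), FCRL5, an Fc receptor-like protein, rose (0.97 ± 0.13) and the chemokine receptor CCR1 fell (−0.71 ± 0.14). Of 16 acetyltransferases and bromodomain readers (0.44, 0.0794), BRPF3 rose (0.76 ± 0.18). This list was called without degrader 1 (0.0312), degrader 3 (0.0307) or degrader 4 (0.0365), with total count scaling (0.0386), with the mitochondrial share as a covariate (8.58e-04) and with GC content and length trends removed (0.0398). Of 15 BCL2 family genes (median 0.01 but mean and test lower, 0.20), BMF, which promotes apoptosis (−0.91 ± 0.10), and BCL2, which restrains it (−0.57 ± 0.13), fell. Of 13 heat shock genes (0.03, 0.595) HSPA6 fell (−1.27 ± 0.25). Among members adjusted over the list alone, 2 MYC targets, 1 p53 target, 1 surface protein, 1 acetyltransferase list gene and 6 heat shock genes rose, and 1, 1, 2, 0, 2 and, in the BCL2 family, 4 fell. The lists with no member called were immunoglobulin and secretory factors (0.07, 0.314), MHC class I (0.25, 0.314) and class II genes (−0.24, 0.395) and unfolded protein response genes (0.21, 0.503). The others were glycine and nucleotide synthesis genes (0.06, 0.539), ribosomal proteins (−0.07, 0.595) and mitochondrially encoded genes (1.23, 0.759), also when adjusted over the list alone. Of their 124 tested members, edgeR called 0, with 14 at an unadjusted p under 0.05, DESeq2 called 6 and limma-voom 1. Without degrader 2, 14 MYC targets, 10 p53 targets, 8 surface proteins, 7 acetyltransferase list genes, 4 BCL2 family genes and 6 heat shock genes rose and 5, 2, 4, 1, 4 and 2 fell. Among the lists with no member called, 4 immunoglobulin and secretory, 0 MHC class II, 9 MHC class I, 12 unfolded protein response, 7 glycine and nucleotide and 4 ribosomal genes then rose and 0, 2, 1, 1, 1 and 0 fell. The medians of the BCL2 family (−0.12) and ribosomal proteins (0.01) turned. In that setting MYC targets (0.11, adjusted p = 0.0469), MHC class I (0.47, 2.88e-04), unfolded protein response (0.25, 0.00322) and glycine and nucleotide synthesis genes (0.17, 0.0326) were called higher. With an estimated correlation these had an adjusted p of 0.482, 0.336, 0.336 and 0.495. All 13 mitochondrially encoded genes fell (−1.64, adjusted p = 6.33e-19; adjusted p = 0.303 with an estimated correlation). XPC, CCR1, BRPF3, BCL2 and HSPA6 lost their calls in the 7 leave-outs that keep degrader 2 (adjusted p up to 0.168). MAP3K6 lost it in 6 of them, all but that of degrader 3 (0.0839), and NOP56 without DMSO 1, 3 or 4 or degrader 1 or 4 (0.0755).

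In the degrader comparison EP300 itself, on chromosome 22 from 41091786 to 41180079 on the plus strand (GRCh38; ENSG00000100393), had 35.8, 45.3, 43.9 and 41.4 CPM in DMSO and 49.9, 141, 48.1 and 49.9 CPM in degrader 1 to 4. Its log2 fold change was 0.79 ± 0.35 (adjusted p = 0.249), and 0.24 (0.0531) without degrader 2. CREBBP, on chromosome 16 from 3725054 to 3880726 on the minus strand (ENSG00000005339), had 26.5 ± 2.56 CPM in DMSO and 43.7 ± 15.3 CPM with the degrader (0.71 ± 0.22, adjusted p = 0.101; 0.44 and 0.00187 without degrader 2). MYC, the proto-oncogene transcription factor, on chromosome 8 from 127735434 to 127741434 on the plus strand (ENSG00000136997), had 48.6 ± 12.6 and 28.7 ± 3.08 CPM (−0.76 ± 0.19, adjusted p = 0.0632) and was called without degrader 2 (−0.77, 0.00294) or DMSO 3 (−0.91, 0.0274). Leave-outs aside, MYC was also called in 4 of the planned other settings and in 2 of those added later. IRF4 lies on chromosome 6 from 391739 to 411447 on the plus strand (ENSG00000137265). The T cell gene CD3E was the only marker of another cell type called (−0.98 ± 0.21, edgeR adjusted p = 0.0348). It lost its call in the 7 leave-outs that keep degrader 2 (adjusted p up to 0.121). Its mean in DMSO was 40.3 CPM of all counts, without TMM scaling. Of the other markers, MS4A1, PAX5, CR2 and BACH2 of earlier B cells, TRAC of T cells, GNLY and NKG7 of NK cells, CSF1R of monocytes and KRT8 and KRT18 of epithelia were tested and not called. No fibroblast or erythroid marker had enough counts for the test. Without degrader 2, PAX5 was called higher (0.82, adjusted p = 0.0213), and BACH2 (−1.08, 3.97e-04) and GNLY (−1.07, 0.00629) were called lower.

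**Figure D3:**
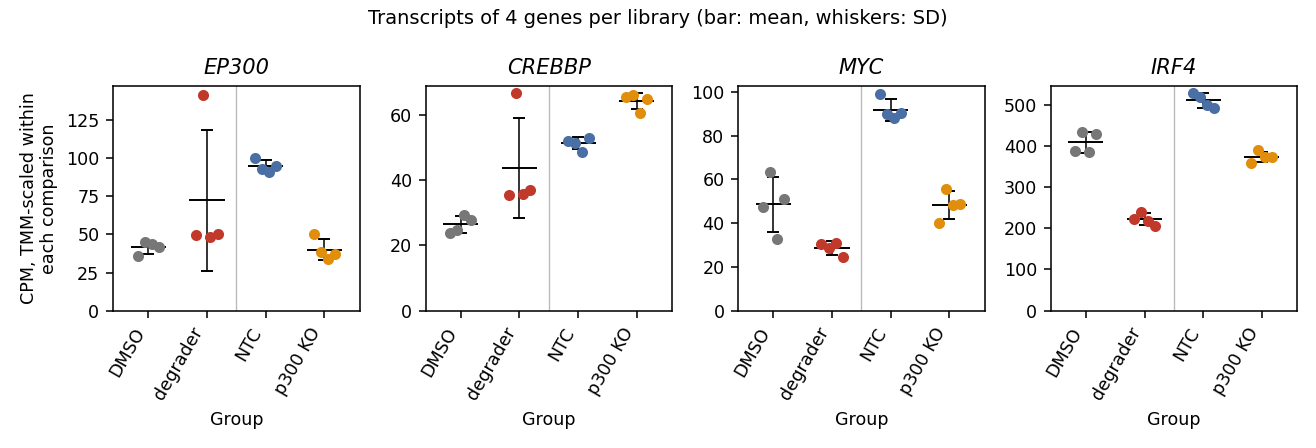
CPM (vertical axis, TMM-scaled within each comparison) of EP300, CREBBP, MYC and IRF4 in each library by group; the bar is the mean and the whiskers are the SD of 4 libraries. EP300 lies between 34 and 50.2 CPM in the KO and between 91.0 and 100 CPM in NTC, and degrader 2 stands apart at 141 CPM.

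Of 15872 genes tested, 755 were called between degrader and DMSO, 260 higher and 495 lower (edgeR's quasi-likelihood test, adjusted p under 0.05), and 315 of them had an absolute log2 fold change of at least 1 (86 higher, 229 lower). Camera called 7 of 24 lists, 4 higher and 3 lower; with an estimated correlation it called 0, with 2 at an unadjusted p under 0.05, and fry called 5. Without degrader 2, camera called 12 lists, 7 higher and 5 lower, and none of them with an estimated correlation (lowest adjusted p = 0.303). Without degrader 2 the count was 6278 of 16297 (2970 higher, 3308 lower), which held all 755 in the same direction. It was 247, 358, 345 and 197 without DMSO 1, 2, 3 and 4, and 215, 220 and 221 without degrader 1, 3 and 4. Total count scaling called 164 genes, 11.6% of them higher against 34.4% in the main result, and moved the median of all genes by −0.14.

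The second comparison set p300 KO cells beside NTC cells. EP300 was at 100, 92.5, 91.0 and 94.6 CPM in NTC 1 to 4 and at 50.2, 38.1, 34 and 37.4 CPM in p300 KO 1 to 4. Its transcript was lower in each KO library and still present (94.5 ± 3.91 and 39.9 ± 7.06 CPM; −1.25 ± 0.11, edgeR adjusted p = 2.2e-04; −1.37 without p300 KO 1). MYC fell from 91.7 ± 4.95 to 48.2 ± 6.31 CPM (−0.93 ± 0.10, adjusted p = 5.06e-04), and IRF4 fell from 510 ± 17.3 to 373 ± 12.8 CPM (−0.45 ± 0.06, 0.00202). CREBBP rose from 51.2 ± 1.84 to 64.2 ± 2.52 CPM (0.32 ± 0.06, adjusted p = 0.0085). It was not called with total count scaling (0.15, 0.701), with no filter on low counts (0.29, 0.117) or in a fit on all 16 libraries (0.27, 0.326).

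The largest falls included genes of U1 small nuclear RNA, a component of the spliceosome: RNVU1-7 went from 79.3 to 0.450 CPM (−7.41 ± 0.20, edgeR adjusted p = 1.22e-07), RNVU1-31 from 33.7 to 0.27 CPM (−6.88 ± 0.17) and RNVU1-26 had −4.03 ± 0.27. U1 genes have near-identical copies, so the value of any member is uncertain. The SE of RNVU1-7 and RNVU1-31 are likely too small. Few reads lie behind 0.450 and 0.27 CPM, and counting error alone can exceed these SE. Other genes that fell were SSBL4P, a pseudogene (−3.59 ± 0.50), KLLN (−2.34 ± 0.14), CD44-DT, a transcript divergent from CD44 (−2.21 ± 0.15), CYP19A1, the aromatase gene (−2.19 ± 0.11). ANKRD34A (−2.12 ± 0.13), the mucin gene MUC1 (−2.00 ± 0.22) and LENG9 (−1.94 ± 0.08) fell too. Genes that rose were FAM161A, a ciliary protein (1.28 ± 0.34), TOP2A, which encodes a DNA topoisomerase of dividing cells (1.19 ± 0.30), MINDY2, a deubiquitinase (1.14 ± 0.32), CEP152, a centrosomal protein (1.08 ± 0.26), and JPX, a long noncoding RNA (0.97 ± 0.24). FOS (0.96 ± 0.14), RIC8B, a chaperone of G proteins (0.95 ± 0.22), the kinetochore gene KNL1 (0.93 ± 0.20), the DNA repair gene RAD51AP1 (0.93 ± 0.25) and MPHOSPH9 (0.93 ± 0.14) rose as well. Without p300 KO 1, the values of FAM161A, TOP2A, MINDY2, CEP152 and RAD51AP1 were 0.79, 0.71, 0.66, 0.71 and 0.58, all called. TOP2A, CEP152, JPX and RAD51AP1 lost their calls without any 1 of the 4 NTC libraries (adjusted p up to 0.0972), and FAM161A and MINDY2 also without p300 KO 4 (up to 0.102). RIC8B lost it without NTC 3 or NTC 4 (0.0592) and KNL1 without NTC 4 (0.0524).

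**Figure D4:**
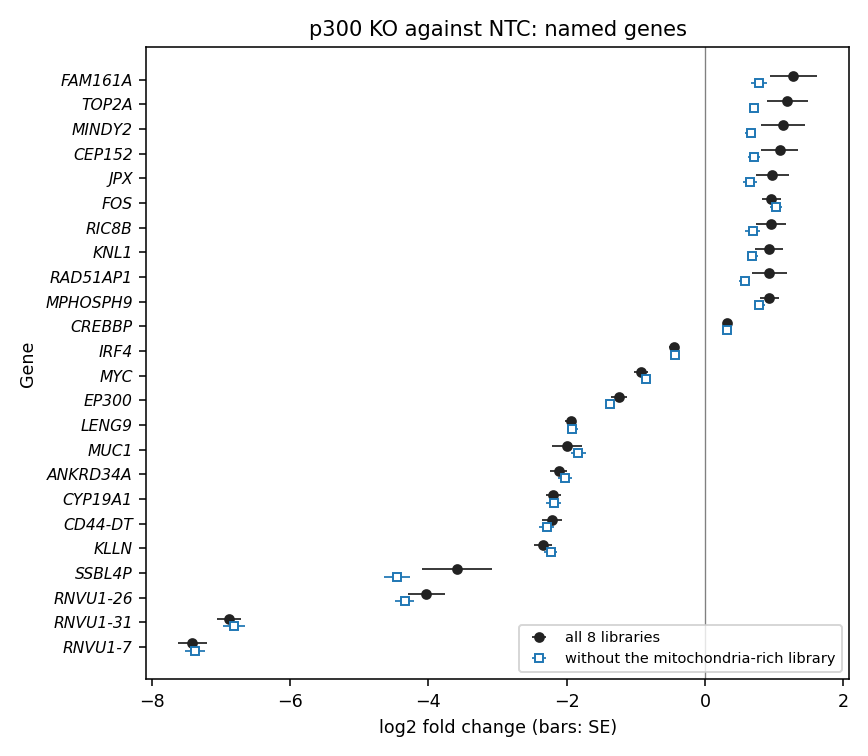
Log2 fold change, p300 KO against NTC (horizontal axis), of the named genes (vertical axis) with all 8 libraries (filled circles) and without the mitochondria-rich library p300 KO 1 (open squares); bars are SE. RNVU1-7 (−7.41) is the lowest, and TOP2A moves from 1.19 to 0.71 when that library is left out.

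Lists of myeloma transcription factors, plasma cell surface proteins, MYC targets, nucleotide synthesis and MAPK output genes were lower. Of 24 myeloma transcription factors, 8 fell, among them MYC, IRF4, the Kruppel-like factor KLF2 (−0.92 ± 0.12) and POU2AF1 (−0.34 ± 0.06), and none of the list rose over all genes (median −0.18; camera adjusted p = 0.00242; adjusted p = 0.264 with an estimated correlation). Of 24 plasma cell surface proteins, 9 fell and 15 were not called. TNFRSF17, the receptor BCMA (−0.60 ± 0.12), GPRC5D (−0.67 ± 0.14), SLAMF7 (−0.34 ± 0.06) and TLR4 (−0.85 ± 0.17) were among those that fell (list median −0.30; adjusted p = 0.00215; adjusted p = 0.472 with an estimated correlation). Of 57 MYC targets, 18 fell, among them the ribosome assembly genes GRWD1 (−0.71 ± 0.08), RRP12 (−0.51 ± 0.08) and NOLC1 (−0.41 ± 0.07) and the folate carrier gene SLC19A1 (−0.61 ± 0.10). PLK4, a kinase of centriole duplication, rose (0.74 ± 0.12; list median −0.22; adjusted p = 3.68e-04; adjusted p = 0.268 with an estimated correlation). Of 22 glycine and nucleotide synthesis genes, 7 fell, among them the purine synthesis genes PFAS (−0.47 ± 0.07), ADSL (−0.38 ± 0.09) and PAICS (−0.27 ± 0.07) and the CTP synthase gene CTPS1 (−0.38 ± 0.10; list median −0.16; adjusted p = 0.0206; adjusted p = 0.643 with an estimated correlation). This list was not called without NTC 1 (0.0504), with total count scaling (0.213) or with the mitochondrial share as a covariate (0.0807), and ADSL lies beside EP300 in a stretch of lower genes. Of 15 MAPK output genes, CCND1, or cyclin D1 (−0.72 ± 0.06), SPRY1 (−0.82 ± 0.20), PHLDA1 (−0.43 ± 0.11), ETV4 (−0.45 ± 0.12) and DUSP4 (−0.27 ± 0.06) fell and 10 were not called (−0.27; adjusted p = 0.0206; adjusted p = 0.268 with an estimated correlation). Total count scaling ended the list's call (0.0628). When p300 KO 1 was left out, 14 myeloma factors, 15 surface proteins, 43 MYC targets, 11 glycine and nucleotide genes and 9 of 16 MAPK output genes fell and 2, 2, 5, 2 and 2 rose, and the 5 lists stayed called. With an estimated correlation in that setting they had an adjusted p of 0.265, 0.357, 0.336, 0.544 and 0.357. Members adjusted over the list alone gave other counts, in that 9, 14, 24, 7 and 5 members of these lists fell and 1, 0, 4, 1 and 0 rose. Calls were lost by PAICS in the 7 leave-outs that keep p300 KO 1 (adjusted p up to 0.0934), by ADSL without NTC 1, 2 or 4 (0.0670) and by PHLDA1 without any 1 of the 4 NTC libraries (0.0770). They were lost by ETV4 in these and without p300 KO 4 (0.0867), by SPRY1 in these and without p300 KO 3 or 4 (0.0689) and by DUSP4 without NTC 1 (0.0550).

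Cell cycle, histone, interferon and mitochondrial lists were higher. Of 24 mitosis genes, 11 rose and none fell, among them the kinase genes CDK1 (0.71 ± 0.10) and BUB1B (0.50 ± 0.06), the phosphatase gene CDC25C (0.65 ± 0.10) and CDC20 (0.34 ± 0.06; list median 0.28; camera adjusted p = 1.87e-05; adjusted p = 0.0772 with an estimated correlation). Of 27 S phase genes, the replication genes CDC6 (0.47 ± 0.10), MCM10 (0.33 ± 0.06) and CDC45 (0.24 ± 0.07) and UHRF1, a regulator of DNA methylation (0.37 ± 0.10), rose. CCNE1, or cyclin E1, fell (−0.37 ± 0.10) and 22 were not called (list median 0.19; adjusted p = 0.0106; adjusted p = 0.475 with an estimated correlation). Total count scaling ended this call (0.151). Of 16 histone genes, H2BC8 rose (0.41 ± 0.11) and H1-10 fell (−0.29 ± 0.07; list median 0.49; adjusted p = 0.0189; adjusted p = 0.264 with an estimated correlation). Of 30 interferon stimulated genes, 8 rose, among them the antiviral GTPase gene MX1 (0.44 ± 0.07) and XAF1 (1.47 ± 0.25). Another 3 fell, namely the nuclease gene ISG20 (−0.51 ± 0.07), OAS1 (−0.40 ± 0.10) and OAS2 (−0.20 ± 0.06; list median 0.27; adjusted p = 0.0362; adjusted p = 0.350 with an estimated correlation). That call was lost without NTC 1 (0.0504) or p300 KO 1 (0.109), at a mean CPM of at least 5 (0.404) and with the mitochondrial share as a covariate (0.131). The histone list lost its call at a mean CPM of at least 5 (0.280). The 13 mitochondrially encoded genes were called as a list with no member called (1.58; adjusted p = 0.0206; adjusted p = 0.742 with an estimated correlation; edgeR 13 at an unadjusted p under 0.05, DESeq2 0 and limma-voom 0). Their median was 0.17 (adjusted p = 0.00131; adjusted p = 0.544 with an estimated correlation) without p300 KO 1 and −0.01 (0.823) with the covariate. With p300 KO 1 left out, 21 mitosis, 19 S phase, 9 histone, 12 interferon stimulated and 11 mitochondrially encoded genes rose and 0, 1, 1, 5 and 0 fell. In this setting the mitosis list was called with an estimated correlation too (adjusted p = 0.0430), and the S phase (0.357) and histone lists (0.336) were not. Adjusted over the list alone, 13, 4, 1, 11 and 13 members of these lists rose and 0, 1, 1, 4 and 0 fell. Calls were lost by CDC45 and OAS2 in the 7 leave-outs that keep p300 KO 1 (adjusted p up to 0.142), by OAS1 without any 1 of the 4 NTC libraries (0.0726) and by UHRF1 in these and without p300 KO 2 (0.0906). They were lost by CCNE1 in these and without p300 KO 3 or 4 (0.0905) and by H2BC8 without NTC 1, 3 or 4 or p300 KO 3 or 4 (0.0939). H1-10 lost its call without NTC 1, NTC 2 or p300 KO 2 (0.0618).

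The other lists were not called. Of 28 p53 targets (median 0.20, camera adjusted p = 0.0546), 5 rose. They were FDXR (0.55 ± 0.08), BTG2 (0.38 ± 0.08), DDB2 (0.29 ± 0.08), POLK (0.47 ± 0.13) and FBXO22 (0.30 ± 0.09), while PLK2 (−1.42 ± 0.15) and AEN (−0.37 ± 0.09) fell. Of 21 NF-kB targets (−0.05, 0.123), 5 fell, among them CCL3 (−1.14 ± 0.11), TRAF1 (−0.95 ± 0.10) and BCL2A1 (−0.47 ± 0.09), and CD83 rose (0.76 ± 0.21). Of 24 ATF4 and amino acid genes (−0.17, 0.184), 4 fell, among them CEBPB (−0.71 ± 0.07) and the amino acid transporter gene SLC7A5 (−0.41 ± 0.07). The 3 that rose were ATF5 (0.59 ± 0.08), DDIT3 (0.66 ± 0.15) and DDIT4 (0.64 ± 0.17). Of 18 immediate early genes (−0.11, 0.95), FOS, BTG2 and ZFP36 (0.57 ± 0.12) rose, and JUNB (−0.57 ± 0.10), IER2 (−0.32 ± 0.08), SRF (−0.25 ± 0.06) and IER5 (−0.33 ± 0.09) fell. Of 15 BCL2 family genes (−0.14, 0.514), BCL2 (−0.74 ± 0.14), BCL2A1 and BCL2L11 (−0.35 ± 0.09) fell and BMF rose (0.32 ± 0.07). Of 16 acetyltransferases and bromodomain readers (0.16, 0.514), EP300 fell, and CREBBP and KAT7 (0.33 ± 0.10) rose. Without p300 KO 1, 16 of 29 p53 targets, 4 NF-kB targets, 3 ATF4 genes, 6 of 19 immediate early genes, 5 BCL2 family genes and 7 acetyltransferase list genes rose and 2, 10, 9, 10, 5 and 3 fell. The p53 list was then called higher (adjusted p = 0.0018; adjusted p = 0.148 with an estimated correlation) and the NF-kB list lower (adjusted p = 0.0216; adjusted p = 0.265 with an estimated correlation). Adjusted over the list alone, 7, 1, 3, 5, 4 and 2 members of these lists rose and 2, 6, 4, 4, 4 and 1 fell. Calls were lost by DDIT4 in the 7 leave-outs that keep p300 KO 1 (adjusted p up to 0.0985) and by POLK, IER5 and CD83 without any 1 of the 4 NTC libraries or p300 KO 2 or 4 (up to 0.107). FBXO22 lost it without any 1 of these NTC libraries or p300 KO 2 or 3 (0.119), and KAT7 without any 1 of them or p300 KO 3 or 4 (0.138). SRF lost it without NTC 1, 3 or 4 or p300 KO 2, 3 or 4 (0.0947), and BCL2L11 without NTC 1, 3 or 4 or p300 KO 2 or 3 (0.0938). DDB2 and IER2 lost it without any 1 of the 4 NTC libraries or p300 KO 4 (0.0925). Calls ended for AEN without any 1 of the 4 NTC libraries (0.0782) and for BMF without NTC 1, 3 or 4 or p300 KO 2 (0.0629). DDIT3 lost its call without NTC 3 or 4 (0.0577) and ZFP36 without NTC 1 or 4 (0.0531).

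The remaining lists had 4 or fewer called members each with all libraries. Of 23 cholesterol synthesis genes (median 0.04, camera adjusted p = 0.455), MVK (0.44), STARD4 (0.50), SC5D (0.33) and MVD (0.26) rose. Of 17 immunoglobulin and secretory factors (−0.10, 0.95), the kinase gene PIM2 rose (0.38 ± 0.11) and MZB1 (−0.27 ± 0.07) and IGHG3 (−1.41 ± 0.36) fell. Of 27 hypoxia targets (−0.11, 0.561), DDIT4 rose and STC2 fell (−0.51 ± 0.07). Of 21 unfolded protein response genes (−0.08, 0.966) DDIT3 rose and SDF2L1 fell (−0.24 ± 0.07). Of 13 MHC class I genes (−0.08, 0.867), the immunoproteasome gene PSMB8 fell (−0.26 ± 0.07). No gene was called among MHC class II genes (0.07, 0.95), heat shock genes (−0.02, 0.796) or ribosomal proteins (−0.05, 0.83). With the mitochondrial list these made 64 tested members, of which edgeR called 0, with 16 at an unadjusted p under 0.05, DESeq2 called 3 and limma-voom 0. Without p300 KO 1, 9 cholesterol, 4 immunoglobulin and secretory, 8 hypoxia, 4 unfolded protein response, 2 MHC class I, 0 MHC class II, 4 heat shock and 0 ribosomal genes rose and 2, 5, 7, 1, 2, 1, 2 and 1 fell. The medians of the hypoxia (0.07), unfolded protein response (0.04), MHC class I (0.04) and MHC class II lists (−0.28) turned in that setting, and none of these lists was called. The test or mean had the opposite sign to the median for the immediate early, unfolded protein response and heat shock lists. Adjusted over the list alone, 4 cholesterol, 2 immunoglobulin and secretory, 0 hypoxia, 1 unfolded protein response and 0 MHC class I genes rose and 0, 3, 1, 0 and 0 fell. MVD, SC5D, PIM2 and PSMB8 lost their calls in the 7 leave-outs that keep p300 KO 1 (adjusted p up to 0.135). STARD4 lost its call without NTC 1, 3 or 4 or p300 KO 2, 3 or 4 (0.0862), and IGHG3 and SDF2L1 without any 1 of the 4 NTC libraries or p300 KO 2 or 4 (up to 0.129). MZB1 lost its call without any 1 of the 4 NTC libraries or p300 KO 4 (0.0819) and MVK without NTC 1, 2 or 3 (0.0624).

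**Figure D5:**
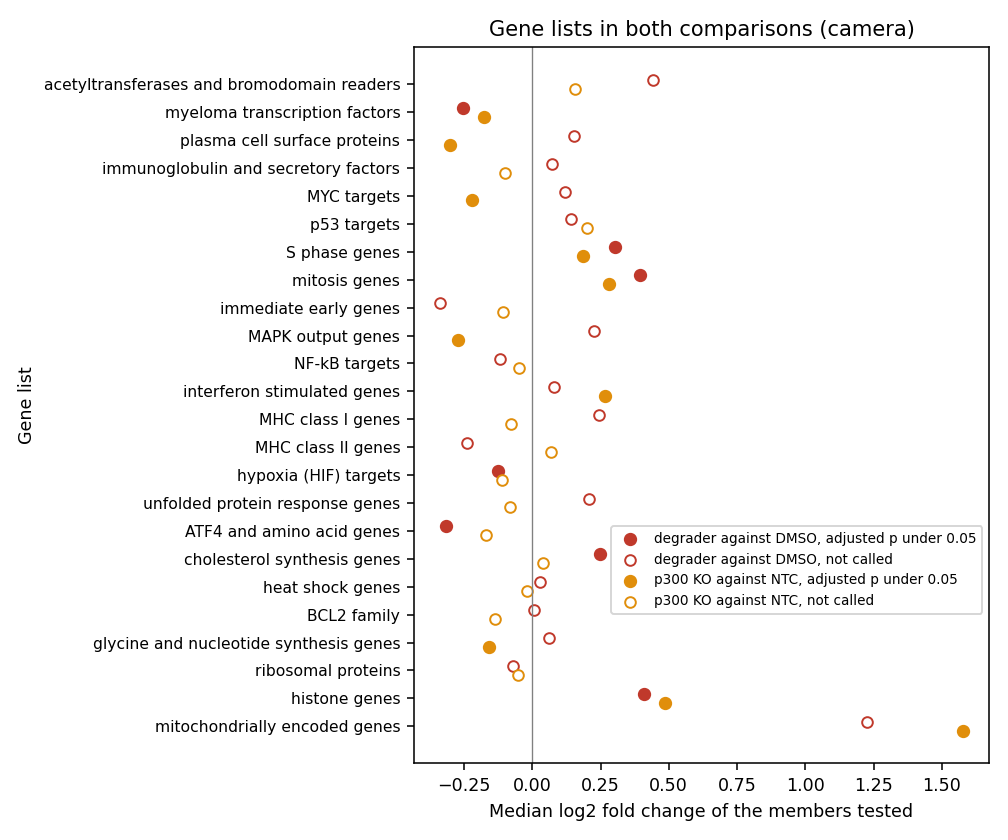
Median log2 fold change of the tested members (horizontal axis) of each of the 24 lists (vertical axis) in both comparisons (red, degrader; orange, KO); filled points have a camera adjusted p under 0.05 and open points do not. S phase, mitosis and histone genes were called higher and myeloma transcription factors lower in both, and with all libraries none of the calls holds with an estimated correlation.

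Markers of earlier B cells fell in the KO from low levels: PAX5 (−1.19, edgeR adjusted p = 0.00269), MS4A1 (−1.12, 0.00844), BCL6 (−0.97, 0.0255) and CD22 (−0.88, 0.0454), while BACH2 (−0.25, 0.358) was not called. TRAC of T cells (−1.13, adjusted p = 1.48e-04), NKG7 of NK cells (−0.66, 0.0187), CSF1R of monocytes (−0.86, 0.00662) and CDH1 of epithelia (−1.48, 0.00524) also fell. CD3E, GNLY, KLRF1, S100A9, COL1A1, KRT8 and KRT18 were tested and not called, and no erythroid marker had enough counts for the test. CD22 lost its call in the 7 leave-outs that keep p300 KO 1 (adjusted p up to 0.124), NKG7 without NTC 1, 2 or 3 or p300 KO 2, 3 or 4 (0.0637) and BCL6 without NTC 2 or 4 or p300 KO 2, 3 or 4 (0.0823). Without p300 KO 1, BACH2 (−0.48, 1.32e-05) and GNLY (−0.60, 3.94e-08) were called lower and COL1A1 higher (0.89, 0.0467).

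Of 17350 genes tested between KO and NTC, 2944 were called, 1081 higher and 1863 lower (edgeR's quasi-likelihood test, adjusted p under 0.05); 672 had an absolute log2 fold change of at least 1, of which 36 were higher and 636 lower. Camera called 10 of 24 lists, 5 higher and 5 lower; with an estimated correlation it called 0, with 3 at an unadjusted p under 0.05, and fry called 11. With an estimated correlation and p300 KO 1 left out, camera called the mitosis list alone (adjusted p = 0.0430). Without p300 KO 1 the count was 7246 of 17706 (3385 higher, 3861 lower), which held all 2944 in the same direction. It was 1617, 1576, 1545 and 1542 without NTC 1, 2, 3 and 4. The share of called genes that were higher was 36.7%, against 4.82% of 1265 with total count scaling, which moved the median of all genes by −0.16, and 26.6% of 2968 with upper quartile scaling.

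The difference between the effects, KO against NTC minus degrader against DMSO, was tested on all 16 libraries. EP300 was lower in this contrast (−2.07 ± 0.37, edgeR adjusted p = 0.00361), whereas IRF4 (0.39 ± 0.13, 0.0885), MYC (−0.20 ± 0.24, 0.691) and CREBBP (−0.42 ± 0.22, 0.299) were not called. The size for EP300 is raised by degrader 2, with 141 CPM of EP300 against 49.9, 48.1 and 49.9 CPM in degrader 1, 3 and 4. EP300 kept its call in all 16 leave-outs of 1 library (edgeR adjusted p up to 0.0104). IRF4 was called without degrader 2 (0.41, 0.0219), without p300 KO 1 (0.45, 0.0347) and without both (0.47, 0.00109). Genes with a higher effect in the KO were DMBT1, a mucosal glycoprotein (3.19 ± 0.38), DDIT4 (2.92 ± 0.33), MYL9 (2.86 ± 0.17), BHLHE40 (2.54 ± 0.25), RHOBTB3 (2.48 ± 0.25) and RN7SL3, a copy of the signal recognition particle RNA (2.46 ± 0.31). Of these, MYL9, BHLHE40 and RHOBTB3 fell with the degrader and had KO values of 0.17, −0.18 and 0.24 that were not called (adjusted p = 0.387, 0.42 and 0.24). DDIT4 and DMBT1 fell with the degrader (DMBT1 −2.30, 0.0473) and rose in the KO (DMBT1 0.82, 4.86e-04). Genes with a lower effect in the KO were RNVU1-7 (−7.32 ± 0.90), RNVU1-31 (−6.22 ± 0.78), the dehydrogenase gene DHRS2 (−3.50 ± 0.26), EGR1 (−2.85 ± 0.22), LENG9 (−2.38 ± 0.22) and TAS1R3 (−2.35 ± 0.18). DHRS2 rose with the degrader (1.85, adjusted p = 0.00264) and fell in the KO (−1.60, 9.32e-05), as did TAS1R3 (−0.68 in the KO, 0.0011). EGR1 was not called in the KO (−0.35, 0.16), except without p300 KO 1 (−0.53, 2.15e-06). In the degrader comparison, DMBT1 lost its call in the 7 leave-outs that keep degrader 2 (adjusted p up to 0.158), and DDIT4 lost its call in the KO in the 7 that keep p300 KO 1 (0.0985).

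As a list, MYC targets had a lower effect in the KO (median −0.33; 6 of 57 called lower, among them NOP56, −1.08, and GRWD1, −0.97; camera adjusted p = 2.91e-05; adjusted p = 0.408 with an estimated correlation). So had plasma cell surface proteins (−0.35; FCRL5 −1.29, TLR4 −1.32, TNFRSF13B −2.06 and CD79B −0.81 lower and CCR1 0.60 higher of 23; adjusted p = 0.0149; adjusted p = 0.898 with an estimated correlation). A lower effect was also seen for MAPK output genes (−0.66; 6 of 16 lower, among them DUSP4, −1.24, and CCND1, −0.68, and DUSP5 higher, 1.07; adjusted p = 0.0155; adjusted p = 0.408 with an estimated correlation). Glycine and nucleotide synthesis genes were called lower (−0.27; adjusted p = 0.0447; adjusted p = 0.898 with an estimated correlation) with 0 of 22 members called by edgeR, 7 at an unadjusted p under 0.05, 3 called by DESeq2 and 0 by limma-voom. Hypoxia targets (0.11; PFKFB4 2.36, DDIT4, KDM3A 1.04 and STC2 0.63 higher and ALDOC −1.20 lower of 27; adjusted p = 0.0355; adjusted p = 0.898 with an estimated correlation) had a higher effect. So had ATF4 and amino acid genes (0.17; 6 of 24 higher, among them DDIT3, 0.88, and ATF5, 0.86; adjusted p = 0.0447; adjusted p = 0.898 with an estimated correlation). Without both mitochondria-rich libraries, 38 MYC targets, 12 of 24 surface proteins, 9 MAPK output genes, 11 glycine and nucleotide genes, 3 hypoxia targets and 4 ATF4 genes were lower and 3, 1, 1, 0, 11 and 9 higher, and no list was called with an estimated correlation (lowest adjusted p = 0.173). The median of hypoxia targets turned to −0.07 without degrader 2 and −0.02 without p300 KO 4. Adjusted over the list alone, 10 MYC targets, 6 surface proteins, 8 MAPK output genes, 0 glycine and nucleotide genes, 1 hypoxia target and 2 ATF4 genes were lower and 2, 1, 1, 0, 7 and 6 higher. Leaving out 1 library ended the call of surface proteins (p300 KO 1, 0.0598), of MAPK output genes (degrader 2, 0.0560) and of hypoxia targets (DMSO 2, degrader 2, NTC 4 and p300 KO 2, 3 or 4, up to 0.274). It ended that of ATF4 genes without DMSO 2 or 3, degrader 2, NTC 1 or 4 or p300 KO 2 or 3 (up to 0.329). Glycine and nucleotide genes lost it without DMSO 1 or 3, degrader 1, 3 or 4, NTC 1 or 4 or p300 KO 1 (up to 0.294). Total count scaling ended those of MAPK output (0.0776), hypoxia (0.293), ATF4 (0.242) and glycine and nucleotide genes (0.219). The leave-out of both mitochondria-rich libraries ended that of ATF4 genes (0.06, 0.0862), and the mitochondrial share as a covariate those of surface proteins (0.216) and glycine and nucleotide genes (0.312). CD79B lost its call in every leave-out but that of degrader 2, and ALDOC and GRWD1 in all but those of degrader 2 and DMSO 2 (adjusted p up to 0.111). CCR1 kept it only without DMSO 1, degrader 1, 2 or 3 or p300 KO 1 (up to 0.0886 in the others). ATF5 lost it without degrader 1, 3 or 4, NTC 2, 3 or 4 or p300 KO 2 (0.0640). TLR4 lost it without DMSO 1, degrader 1 or degrader 3 (0.0563) and TNFRSF13B without DMSO 1 or NTC 2 (0.0514).

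The other 18 lists were not called in the difference. The closest was cholesterol synthesis (median −0.27, camera adjusted p = 0.0513; 1 of 23 lower), followed by S phase (−0.16, 0.223), interferon stimulated (0.23, 0.223; 6 of 31 higher and 5 lower), immediate early (0.21, 0.283), MHC class I (−0.37, 0.283) and mitochondrially encoded genes (0.27, 0.283). Acetyltransferases and bromodomain readers (−0.29) and immunoglobulin and secretory factors (−0.19) had an adjusted p of 0.317, MHC class II genes (0.29) of 0.476 and histone genes (−0.01) of 0.478. Unfolded protein response (−0.25) and heat shock genes (−0.24) had 0.703, myeloma transcription factors (0.02) and p53 targets (−0.01) 0.809, and mitosis (−0.12), NF-kB (−0.05), BCL2 family (−0.21) and ribosomal genes 0.855. Without degrader 2, S phase (−0.31, 0.0232), MHC class I (−0.67, 0.0018), unfolded protein response (−0.34, 0.0187) and cholesterol synthesis genes (−0.37, 0.00106) were called lower and mitochondrially encoded genes higher (3.05, 3.18e-06). Cholesterol synthesis genes were also called without DMSO 2 (−0.30, 0.0347), NTC 3 (−0.27, 0.0471) or p300 KO 4 (−0.32, 0.0259). Without both mitochondria-rich libraries, S phase (8 of 27 lower), MHC class I (9 of 13 lower, 1 higher), unfolded protein response (9 of 21 lower, 2 higher) and cholesterol synthesis genes (10 of 23 lower) were called lower. The 13 mitochondrially encoded genes were then higher. With an estimated correlation and without both libraries, the adjusted p of these 5 lists was 0.644, 0.561, 0.561, 0.536 and 0.173. Median, mean and test differed in sign for myeloma transcription factors, p53, NF-kB, heat shock, BCL2 family, ribosomal and histone genes.

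In the difference 1189 of 18068 genes were called, 509 higher in the KO effect and 680 lower (edgeR, all 16 libraries); 651 had an absolute log2 value of at least 1. Camera called 6 of 24 lists (2 higher, 4 lower), 3 without NTC 4, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05; fry called 4. The gene count was 4611 without degrader 2, 766 without NTC 4, and 5901 of 18432 without both mitochondria-rich libraries, which held all 1189 in the same direction. Each experiment has its own controls, so a difference between the experiments cannot be told apart from a difference between short degradation and KO.

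Genes called in both comparisons moved mostly the same way. PECAM1, an adhesion molecule of blood cells and endothelium, fell with the degrader (−1.07) and in the KO (−0.94), as did CCL3 (−0.86 and −1.14). FAM167A (−1.20 and −1.16), PNPLA7, a lysophospholipase (−1.45 and −0.77), NR1D1, a repressor of the circadian clock (−0.80 and −0.76), and TNFRSF14-AS1 (−0.98 and −0.96) also fell in both. PRC1, which organises the mitotic spindle midzone, rose in both (0.58 and 0.50), as did ELP4 (0.62 and 0.63), CSRNP2 (0.56 and 0.62), TULP3 (0.58 and 0.50), SPINDOC (0.68 and 0.47) and BTN2A2 (0.75 and 0.45). Over the 15443 genes tested in both, 138 fell in both against 45.4 for independent lists and 42 rose in both against 17.9. In opposite directions, 27 rose with the degrader and fell in the KO against 24.2, and 19 did the reverse against 33.7. Of the 226 genes called in both, 79.6% had the same sign. Without both mitochondria-rich libraries the ratio to that number was smaller, with 886 lower in both against 628 and 976 higher in both against 628, and 67.6% of 2756 had the same sign. The log2 fold changes correlated across genes at Pearson's r = 0.25. Genes are not independent replicates, and in exact two-sided tests over the 35 splits of the libraries of either experiment p was 1 for the degrader and 0.0571 for the KO. The smallest possible p is 0.0286. Without both mitochondria-rich libraries r was 0.16 (exact p = 0.0857 and 0.257), and without degrader 2 alone it was −0.09. With the degrader, CCL3, ELP4 and CSRNP2 lost their calls in the 7 leave-outs that keep degrader 2 (adjusted p up to 0.146). TULP3, PRC1 and NR1D1 lost theirs in these less that of DMSO 3, DMSO 2 and DMSO 4, respectively (up to 0.108), TNFRSF14-AS1 without DMSO 4, degrader 1 or degrader 4 (0.0579) and FAM167A without degrader 3 (0.0503). In the KO, SPINDOC lost it without any 1 of the 4 NTC libraries or p300 KO 2 or 3 (0.103).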

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

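The tests on the mitochondria-rich libraries, on the U1 genes and on the genes beside EP300 were chosen after seeing the results; the splits of the libraries and the tests of the agreement and of the degrader effects without those libraries were written before.

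In 11 of 48 sets of 4 values, which are several measures in each group of 4 libraries, 1 library lay far from the other 3 by Dixon's criterion, where chance picks about 1 in 20. DMSO 1 had the first of these, with 26843 genes detected. Degrader 2 had 5 of them. Its mitochondrial share was 64.9% (exact binomial 95% interval 64.8 to 64.9%), its 10 highest genes took 59.7% of counts (59.6 to 59.7%) and immunoglobulin genes 0.169% (0.167 to 0.171%). EP300 was at 141 CPM and CREBBP at 66.6 CPM. The library p300 KO 1 had 5 as well, with a mitochondrial share of 47.7% (47.7 to 47.8%), 44.0% in the 10 highest genes (44.0 to 44.0%), 0.374% in immunoglobulin genes (0.371 to 0.377%), 95.7% in protein-coding genes (95.7 to 95.7%) and 2.53% in lncRNA genes (2.52 to 2.54%). The intervals cover counting error only.

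Transcripts of the nucleus as well as of mitochondria set degrader 2 and p300 KO 1 apart, which might come from dilution, a swapped label, or a change of RNA quality or cell state. Dilution by mitochondrial reads would leave nuclear genes near their usual ratios, but across 10390 nuclear genes the median absolute deviation of these libraries was 6.99 and 3.91 times that of the others, where dilution alone predicted at most 1.5. A swap with an NTC library is unlikely for p300 KO 1, because its EP300 value lies at a log2 ratio of −1.03 to the lowest NTC library. EP300 cannot speak on a swap with DMSO, since p300 KO 1 had 51.0 CPM of nuclear counts and DMSO 48.0 to 62.7. In degrader 2, IRF4 was at 241 CPM against at least 384 CPM in DMSO, and EGR1 at 26.2 CPM against at most 6.58 CPM, as in the other degrader libraries. The deviations of the 2 libraries correlated across nuclear genes at r = 0.826, so a change of the same kind may have struck both, and no integrity value is given in the sources used here to tell degraded RNA from a stressed culture.

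U1 genes, which encode an RNA of the spliceosome, may be lower in the KO through loss of p300, through reads shared between copies, or because the NTC libraries stand apart. Summed over copies, U1 counts as CPM of nuclear counts were 210 ± 23.9 in NTC, 17.4 ± 6.61 in the KO, 22 ± 2.98 in DMSO and 12.9 ± 5.15 with the degrader (SD, n = 4 each). Counted reads that moved between copies would keep the sum, yet the lowest NTC library had 6.60 times the sum of the highest KO library. Reads that map to several places may have been dropped, since their treatment is not stated, and the sum cannot test for that. The highest DMSO library had 0.137 of the lowest NTC library, so the KO lay nearer DMSO than NTC did. The NTC libraries may thus stand apart, possibly through culture or RNA preparation. DMSO belongs to the other experiment, so a higher U1 level in the second experiment with a fall in the KO cannot be told apart from this. Loss of p300 remains open. The U1 sum was 8.80, 10.4 and 11.9 in degrader 1, 3 and 4, below each DMSO library (17.9 to 24.6). In degrader 2 it was 20.3, within the range of DMSO. Only 2 of the 11 U1 genes that fell passed the count filter in the degrader comparison, where their median was −1.26.

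EP300 itself was at 48.0, 62.7, 58.0 and 56.1 CPM of nuclear counts in DMSO, 116, 107, 104 and 109 in NTC and 51.0, 44.3, 39.7 and 43.4 in the KO, so that DMSO lay nearer the KO than NTC.

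The effects differed between KO and degrader, by the test of the difference, for EP300 (−2.07), DHRS2 (−3.50), EGR1 (−2.85), LENG9 (−2.38), TAS1R3 (−2.35), RNVU1-7 (−7.32) and RNVU1-31 (−6.22), which were lower in the KO effect. They differed in the other direction for DMBT1 (3.19), DDIT4 (2.92), MYL9 (2.86), BHLHE40 (2.54), RHOBTB3 (2.48) and RN7SL3 (2.46). Among lists, the median differed by −0.35 for plasma cell surface proteins, −0.33 for MYC targets, −0.66 for MAPK output genes, −0.27 for glycine and nucleotide synthesis genes, 0.11 for hypoxia targets and 0.17 for ATF4 and amino acid genes, and none of the 6 calls held with an estimated correlation (adjusted p of 0.408 or 0.898).

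Splits of the libraries into other groups of 4 asked whether any grouping gives as many called genes as the labels. Of 35 splits, 1 reached the 755 genes of the degrader comparison, the labels themselves, and the highest other split called 0; edgeR found up to 4842 genes at an unadjusted p under 0.05 in other splits, against 3289 with the labels, and no other tool was run on them. For the KO it was 1 of 35, with 0 in the highest other split, up to 2022 unadjusted and 5837 with the labels. Without the mitochondria-rich libraries it was 1 of 35 for each, with up to 3113 genes in another split for the degrader, in which DMSO 1, 3 and 4 stood against the rest, and 1 for the KO. For the difference 3 of 100 splits, the labels among them, reached 1189 genes, with up to 2888 in another split. Without those libraries only the labels, 1 of 100, reached 5901, with up to 3182 in another split. The split with 3113 genes kept most of the grouping by label, so its calls cannot be told apart from the effect of the labels. The same holds for the split with 4842 unadjusted genes, which put DMSO 2 with degrader 1, 3 and 4. Every split of a comparison other than the labels mixed both labels within a group. An effect of the labels then adds to the spread within that group and lowers the calls. The 0 calls of other splits therefore cannot exclude chance. How much of the labels the other splits for the difference kept was not examined. Their calls therefore cannot show whether structure other than the labels yields called genes.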

How the results depend on the processing

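Alternatives with sample quality weights, the mitochondrial share as a covariate, mitochondrial genes left out, GC content and length trends removed, or both mitochondria-rich libraries left out were chosen after seeing the data; the others were planned. Of the values of single genes, 4522 kept the side of the threshold without a reversal, 984 lost the call, 31 gained it and 1 reversed. For lists these were 1305, 77, 50 and 2. A gene or list counts as reversed only if it was called in the main result or in the alternative. For lists the direction is that of the list test, so the turned medians given above are mostly not counted as reversed. EP300 fell in the KO under every alternative.

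In the degrader comparison 755 genes became 164 with total count scaling, 394 with no filter, 1796 with DESeq2, 2294 in a fit on all 16 libraries, 315 at an absolute log2 fold change of at least 1, 7616 with sample quality weights and 5663 with the mitochondrial share as a covariate. In the KO comparison 2944 became 1265 with total count scaling, 1484 in the fit on all 16, 672 at the minimum of 1, 6871 with weights and 7008 with the covariate. In the difference 1189 became 319 with total count scaling, 585 with no filter, 2095 with DESeq2, 651 at the minimum of 1, 5901 without both mitochondria-rich libraries, 6835 with weights and 4546 with the covariate. With 1 library left out, the ranges were 197 to 6278, 1542 to 7246 and 766 to 4611. The top of each range is the leave-out of a mitochondria-rich library; the other causes were not tested.

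With the degrader, EP300 (0.79, not called) was called with weights (0.26, adjusted p = 0.0253) and the covariate (0.76, 4.83e-06), and leave-outs gave 0.24 to 0.94. CREBBP (0.71, not called) was called with DESeq2 (0.72, 0.0224), all 16 libraries (0.69, 0.00917), weights (0.44, 3.72e-04), the covariate (0.75, 8.3e-07) and GC content and length trends removed (0.68, 0.0136), with leave-outs from 0.44 to 0.81. In the KO, CREBBP lost its call with total count scaling (0.15, 0.701), no filter (0.29, 0.117) and all 16 libraries (0.27, 0.326). The causes were not tested.

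Of 24 lists, 7, 10 and 6 were called, and 0, 0 and 0 with an estimated correlation. With 1 library left out, 6 to 12 were called for the degrader and 8 to 11 for the KO; for the difference it was from 3, without NTC 4, to 8, without degrader 2. The covariate gave 11 for the degrader, total count scaling 3 and leaving out both mitochondria-rich libraries 10 for the difference. Lists that gained a call with the degrader, leave-outs and the other list test (fry) aside, included acetyltransferases and bromodomain readers with a replicate block (adjusted p = 0.0343), immunoglobulin and secretory factors with total count scaling (0.0128), NF-kB targets (0.00249) and the BCL2 family (0.0414) at a mean CPM of at least 5, and immediate early genes (0.00338), NF-kB targets (0.00866) and ribosomal proteins (0.0315) with the covariate. In the KO, also with these aside, p53 targets gained it at a mean CPM of at least 5 (0.0384) and with the covariate (7.6e-04), as did NF-kB targets (0.0185) and cholesterol synthesis genes (0.0292) with the covariate. The agreement of the effects, r = 0.25 with a jackknife SE of 0.35, ran from −0.0900, a reversal, without degrader 2 to 0.322 without degrader 1. Reversed too were mitochondrially encoded genes with the degrader without degrader 2 (−1.64; up to 1.58 without another library), hypoxia targets in the KO with the covariate (0.11, adjusted p = 0.0215) and SDF2L1 in the KO with GC content and length trends removed (0.00635, 0.959). The causes were not tested.

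A replicate block gave 24, 1304 and 306 genes. Whether the numbers pair the libraries stays open. Deviations of genes from their group mean correlated between DMSO and degrader libraries of the same number at −0.0249, −0.420, −0.438 and 0.130. Between NTC and KO libraries of the same number they correlated at −0.201, 0.0724, −0.229 and −0.0345. The group means include degrader 2 and p300 KO 1, so these values cannot settle pairing. DMSO 2, for example, had 0.435, 0.378 and 0.243 with degrader 1, 3 and 4, whose numbers differ from its own.

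The limit that depth sets was not tested. Degrader 2 held 4.42 M (M, mega) and p300 KO 1 8.66 M nuclear counts, and without them the common biological coefficient of variation went from 0.279 to 0.104 with the degrader and from 0.165 to 0.0498 in the KO.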

Other observations

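The tests on the genes beside EP300 were chosen after seeing the result; those on the degrader effects and on the agreement were written before.

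Classes of genes were counted in the KO without a test between classes. With an absolute log2 fold change of at least 1, 4 of 948 long intergenic genes rose and 129 fell, 4 of 1244 antisense genes rose and 127 fell, and 0 of 43 small nuclear RNA genes rose and 20 fell. In the small nucleolar class 0 of 30 rose and 3 fell (median of all 30 0.17), in the remaining classes 11 of 1884 rose and 93 fell (median 0.15), and 17 of 13201 protein-coding genes rose and 264 fell. Leaving out p300 KO 1, the genes that rose and fell numbered 4 and 182 long intergenic, 4 and 197 antisense, 0 and 25 small nuclear, 0 and 4 small nucleolar, 20 and 161 remaining, and 25 and 424 protein-coding genes. With the degrader they were, in the same order, 3 and 20 of 673, 1 and 20 of 1011, 0 and 2 of 27, 0 and 0 of 48, 3 and 29 of 1698, and 79 and 158 of 12415. Without degrader 2 they were 16 and 112, 2 and 210, 0 and 17, 0 and 12, 19 and 387, and 218 and 441.

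Genes beside EP300 were lower in the KO. Of the 20 nearest expressed genes, on chromosome 22 from 39529093 to 41589890, 18 had a lower value and 9 fell, among them ADSL (−0.38), which acts in purine synthesis, the peroxisomal carrier gene SLC25A17 (−0.50), XPNPEP3 (−0.48), RBX1, a subunit of cullin ubiquitin ligases (−0.60), L3MBTL2 (−0.32), RANGAP1 (−0.60), ZC3H7B (−0.46) and CSDC2 (−0.91). None rose, and the median was −0.30. Of these, XPNPEP3 lost its call in the 7 leave-outs that keep p300 KO 1 (adjusted p up to 0.115), ADSL without NTC 1, 2 or 4 (0.0670) and L3MBTL2 without NTC 1, NTC 4 or p300 KO 4 (0.0611).

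Such a run might be chance, an effect of p300 on its neighbours, or a change of DNA copy number around EP300. Of 12540 windows of 20 genes, 18 (0.144%) had a median as low, which leaves little room for chance. An effect of p300 loss present at 6 h is not seen, because the median of the same genes with the degrader was 0.0211 without degrader 2. The 18 lower genes could reflect a lost copy of part of chromosome 22 in the KO cells, but RNA alone cannot measure DNA, and a slow effect of lasting p300 loss stays open.

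RNA quality of the DMSO libraries, which had more mitochondrial counts than degrader 1, 3 and 4, might account for part of the degrader effects. The degrader effect without degrader 2 correlated at r = −0.409 with the deviation of p300 KO 1 across nuclear genes, which leaves the question open. With this trend removed, 10 of 11 lists (90.9%) kept their sign and at least 50% of their median, so the trend as fitted does not account for most of them. It was fitted on the deviation of 1 library of the other experiment and may be removed only in part, so RNA quality stays open as a cause. The test used nuclear genes, so the mitochondrially encoded list, also called without degrader 2, was not part of it. Glycine and nucleotide synthesis genes kept their sign but less than 50%, with a median that went from 0.17 to 0.06. The medians of hypoxia targets (−0.11 to −0.30) and MYC targets (0.11 to 0.20) grew in size. Only genes with a mean count of at least 100 were used, so some lists lost members. For ATF4 genes, 20 members with a median of −0.16 before removal stood in for 24 with −0.39.

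With all libraries, the sign of the correlation of the KO and degrader effects followed degrader 2. In the splits of the degrader comparison, r was 0.254 to 0.480 wherever degrader 2 was grouped with degrader 1. It was −0.489 to −0.301 wherever it was not. Leaving out degrader 2 alone gave r = −0.0900. Without both mitochondria-rich libraries the correlation was r = 0.162, and another split reached an absolute r of 0.232. With all libraries it was r = 0.254, and other splits already reached 0.489 for the degrader and 0.259 for the KO. The real r was thus exceeded with and without those libraries.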
